A study of Mus musculus with 12 samples.

How the data were processed

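The series holds 12 libraries of ribosome-associated RNA pulled down from parvalbumin interneurons of the mouse cortex (C57BL/6), in 4 groups of 3: wild type and Nptx2 KO, each kept in group or single housing for at least 4 weeks from weaning, which the labels call social stress. The labels state 3 biological replicates per group. Libraries were made with a stranded mRNA kit, per the labels' protocols. HISAT2, StringTie, limma and GRCm38 are named in the submitters' processing notes, whose versions are not given in the sources used here. No library of RNA before pulldown was analysed here, so enrichment could not be measured.

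The authors deposited one table with a log2(FPKM + 1) value per gene and library , with columns named by a barcode and group and without replicate numbers. Libraries are therefore named by group and barcode. The table was tested on its values: repeating quantile normalization moved no value by more than 0.00883 log2, and median-ratio factors were 0.998 to 1.01, so the deposited values were already quantile normalized, which removes any difference between libraries in overall distribution. No value came as whole reads, so depth is unknown and no counting interval could be given. The p-values and log2 differences of the authors' own comparisons, KO against wild type in each housing condition, stand in the same deposited table. The score values there, moderated t and F statistics, were computed by the authors with limma before deposit, as deposited and per the file headers. Repeating them with limma without a variance trend on all deposited genes left differences of at most 5.00e-06 in t. Gene IDs were matched to GENCODE M21 on GRCm38: 13131 were found and 59 were not. No 2 libraries held identical values.

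Genes with an FPKM of at least 1 in at least 3 libraries were tested, 12716 in all. A mean per group was fitted to the deposited values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a variance trend; 8 residual and 2.18 prior degrees of freedom), with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. All 12 libraries entered each fit. The 7 comparisons were single against group housing in wild type and in KO, KO against wild type in each housing condition, the interaction, and the average effects of housing and genotype. A log2 change is on the log2(FPKM + 1) scale, which understates changes of low genes. The 4 groups are shared among comparisons, so that a high or low group appears in more than 1 of them.

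Gene lists were fixed before the data were examined. They were the pentraxin and AMPA receptor complex, other glutamate receptors, parvalbumin interneuron markers, GABA receptors and handling, ion channels, perineuronal net, synaptic vesicle release, immediate early genes, glucocorticoid-responsive genes, stress hormones and neuropeptides, neurotrophin and neuregulin signalling, synaptic adhesion, exome-implicated schizophrenia genes, oxidative phosphorylation, mitochondrially encoded proteins, cytosolic and mitochondrial ribosomal proteins, unfolded protein response, heat shock proteins, cholesterol synthesis, proteasome, interferon response, complement, markers of excitatory neurons, other interneurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, choroid plexus, striatal, thalamic and cerebellar neurons and blood, and sex-linked genes. The 34 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, and beside it with an estimated correlation and with fry. Mitochondrially encoded proteins had 0 tested members and choroid plexus markers 2, so neither was tested. A list score is the mean over members of each gene's deviation from its mean over the 12 libraries.

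Named genes were chosen by a rule written before the data were examined: Nptx2, Nptx1, Nptxr, Gria4 and Pvalb, up to 8 genes per direction past the threshold (filled to 4 by unadjusted p), and up to 4 members per list. Genes with predicted or clone names and pseudogenes fell outside it, and those named were chosen after their values were seen. Pseudogenes were matched to protein-coding transcripts with BLAST 2.17.0, requiring 50% of the transcript aligned.

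The fit was tested on simulated log2 values drawn from the real gene means and residual SDs among 12716 genes, of which 100 were changed by 0.5 and 50 each by 1 and 2. For single housing in wild type it recovered 70.0% of genes changed by 0.5, 88.0% of those changed by 1 and 94.0% of those changed by 2 on the log2 scale, with 10 false calls among 171. For KO in group housing it recovered 69.0%, 90.0% and 94.0%, with 6 false calls among 167. For single housing in KO it recovered 72.0%, 88.0% and 96.0% with 13 false calls among 177, and for KO in single housing 69.0%, 84.0% and 96.0% with 8 among 167. With no change 0 lists were called, and an immediate early list lowered by 0.3 was called in each of the 4 comparisons. Simulated genes vary independently, unlike real ones. Changing so many genes at once also eases the Benjamini-Hochberg cut-off. The real comparisons called 0 to 5 genes, so these shares overstate the recovery where few genes change.

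Alternatives written before the data were examined were no filter, a pseudocount of 0.1, quantile normalization, median-ratio scaling, the compared groups only, no variance trend, a replicate block and leaving out each library. Added after seeing the data were the authors' settings, a term for Y-linked signal, and leaving out chromosome 5 and pseudogenes whose parent lies near Nptx2. In the closing section 3 tests or limits were changed after their values were seen, and the values before and after are given there: the genotype position of library CTTGTA, the test of housing or genotype for the amino acid response and the test of pseudogenes with a parent near Nptx2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.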

Results

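Ribosome-associated RNA of parvalbumin interneurons was sequenced from mouse cortex. Parvalbumin interneurons are fast-spiking GABAergic cells, and in RiboTag mice a tagged ribosomal protein is switched on by Cre, here from the parvalbumin locus, so that ribosomes of these cells can be pulled down with the RNA they carry. The design crossed genotype with housing after weaning, giving 4 groups of 3 libraries: wild type in group housing, wild type in single housing, Nptx2 KO in group housing and Nptx2 KO in single housing. Nptx2 encodes a secreted neuronal pentraxin that clusters AMPA-type glutamate receptors at excitatory synapses on parvalbumin interneurons. Expression was deposited as log2(FPKM + 1) per gene, and 12716 genes were tested. The sequencing depth is unknown because the table holds no counts, and every library had the same sum of 412903 FPKM because the values were already quantile normalized. Correlations between libraries ran from 0.980 to 0.986 within groups and from 0.980 to 0.986 between groups.

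The deleted gene was examined first. Nptx2 (ENSMUSG00000059991, GRCm38 chromosome 5, 144545902 to 144557478) was not lower in the libraries labelled KO. Its level was 2.42 ± 0.17 in group-housed wild type, 2.58 ± 0.19 in the group-housed libraries labelled KO, 2.35 ± 0.10 in single-housed wild type and 2.54 ± 0.13 in the single-housed libraries labelled KO (log2(FPKM + 1), mean ± SD, n = 3 each). The 6 libraries labelled KO spanned 2.37 to 2.74 and the 6 wild-type libraries 2.23 to 2.62. The difference was +0.15 ± 0.12 in group housing and +0.19 ± 0.12 in single housing (log2 ± SE, limma, adjusted p = 1 and 0.697). Which part of the gene the mutation removes is not given in the sources used here, so a value for the whole gene cannot check the genotype, and genotypes below are those of the labels. Pvalb, the calcium buffer that marks the targeted cells, lay between 9.65 and 10.28 in all 12 libraries. The genes of the other pentraxins and of an AMPA receptor subunit did not pass the test in any comparison: Nptx1 stood at 3.07 to 3.57, Nptxr at 5.18 to 5.42 and Gria4 at 5.77 to 5.97.

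Y-linked transcripts differed between housing conditions. Ddx3y and Eif2s3y, which are transcribed from the Y chromosome, were listed at 0 in all 6 group-housed libraries and in the single-housed KO library CAGATC. The 3 single-housed wild-type libraries had 3.21 to 3.53 for Ddx3y, and the single-housed KO libraries CTTGTA and AGTCAA had 3.62 and 3.45. Eif2s3x, an X-linked gene that escapes X inactivation, was at 5.22 to 5.30 in those 5 libraries and at 5.81 to 6.01 in the other 7. In wild type, housing and Y-linked signal therefore separated the libraries identically, and no value within a sex could be had for that comparison.

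**Figure D1:**
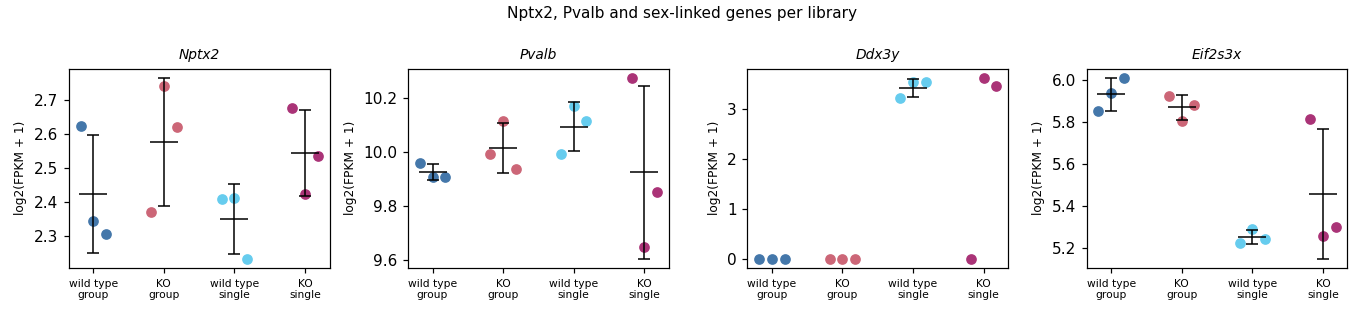
Levels of Nptx2, Pvalb, the Y-linked gene Ddx3y and the X-linked gene Eif2s3x in each library, on the log2(FPKM + 1) scale, by genotype and housing. Points are libraries, horizontal bars are group means and whiskers are SD (n = 3), left out for groups with a library at 0. Nptx2 spans 2.37 to 2.74 in the KO libraries and 2.23 to 2.62 in wild type, and Ddx3y is at 0 in all 6 group-housed libraries.

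Single housing was first compared with group housing in wild type, which asks how isolation after weaning altered translated RNA in these interneurons. Transcripts of neuronal activity genes fell: Fos dropped by 1.91 ± 0.23 (log2 ± SE) from 3.74 ± 0.31 to 1.83 ± 0.07, and Egr1 dropped by 1.74 ± 0.21 from 4.12 ± 0.34 to 2.38 ± 0.08 (mean ± SD, n = 3). Both are transcription factors induced within minutes by synaptic activity. Fhdc1, which encodes an inverted formin that acts on actin and microtubules, fell by 0.84 ± 0.08. All 3 single-housed wild-type values of each of these genes lay below all 3 group-housed values. With limma and Benjamini-Hochberg adjustment the adjusted p was 0.0225 for Fos, 0.0225 for Egr1 and 0.00938 for Fhdc1.

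In all, 5 genes passed in this comparison, 1 higher and 4 lower, and 1560 had an unadjusted p under 0.05 where 635.8 are expected by chance. The other 2 genes, named after their values were seen, were the pseudogene 2700099C18Rik, which rose by 1.08 ± 0.12, and A530032D15Rik, which was listed at 0 in all 3 single-housed wild-type libraries and at 0.70 to 1.22 in the group-housed ones. Fos lies on chromosome 12 (85473890 to 85477273), Egr1 on chromosome 18 (34859823 to 34864984) and Fhdc1 on chromosome 3 (84442198 to 84480429). Among rises that did not pass, the named genes with the smallest p were Trmu (+0.56 ± 0.08, adjusted p = 0.0923) and Neurl1a (+0.36 ± 0.05, adjusted p = 0.0923). Ddx3y and Eif2s3y, at +3.42 and +3.29, did not pass either. The fit pools the spread of all groups, and single-housed KO mixes libraries with and without Y-linked signal. On the compared groups alone both passed (limma, adjusted p = 2.20e-04 and 4.61e-05). The 5 calls therefore set no limit to a sex difference. The split of libraries under other observations is unequal between these groups, so the counts may carry it too.

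Immediate early genes were lower as a list by camera with its preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.0996). Of the 33 tested, 29 had lower values in single-housed wild type, the median difference was −0.43, 2 passed over all genes, and 19 passed when adjusted over the list alone. After Fos and Egr1 the members with the smallest p were Dusp6 (−0.45 ± 0.07), a phosphatase that restrains ERK signalling, and Npas4 (−0.73 ± 0.14), a neuron-specific activity-dependent transcription factor. Of 15 heat shock proteins 13 were lower and 8 passed when adjusted over the list alone, and the list call was lost in the same way (0.102). The chaperones Hspa1a (−0.56 ± 0.11), Hspa1b (−0.60 ± 0.12), Hsph1 (−0.70 ± 0.17) and Cryab (−0.94 ± 0.19) had the smallest p. In the unfolded protein response list, whose call was also lost (0.127), 24 of 25 genes were lower, and 9 passed when adjusted over the list alone, among them Manf (−0.42 ± 0.11), Hsp90b1 (−0.42 ± 0.10), Pdia6 (−0.42 ± 0.11) and Dnajb11 (−0.27 ± 0.08). The group-housed wild-type libraries did not move together on this list: its score was 0.162 in CCGTCC and 0.286 in GTCCGC, which also had high amino acid response genes, and −0.0103 in AGTTCC, against −0.323 to −0.225 in single housing.

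The lists of stress hormones and neuropeptides and of other interneuron markers were called as lower with the preset correlation and not with an estimated one (adjusted p = 0.0996 and 0.162). In the first 17 of 22 genes were lower, and 2 passed when adjusted over the list alone, Tac1 (−0.42 ± 0.10) and Sst (−0.44 ± 0.12), which encode substance P and somatostatin. Npy, for neuropeptide Y, was at −1.13 ± 0.36. Of 13 markers of other interneurons 11 were lower, and 5 passed over the list alone, among them Lamp5 (−0.55 ± 0.11) and Cnr1 (−0.28 ± 0.09). These 2 lists share Npy, Sst and other neuropeptides. Their scores too were highest in the 5 libraries with high amino acid response genes, of which group-housed wild type held 2 and single-housed wild type 0. In AGTTCC, the group-housed library outside these, they were −0.0123 and −0.0575, against −0.159 to −0.0892 and −0.240 to −0.125 in single housing. Parvalbumin interneuron markers had 17 of 27 lower, with 1 past the threshold over the list alone, Tac1, which the list shares with the neuropeptides. Pthlh was at −0.37 ± 0.11, Scn1a at −0.41 ± 0.13 and Pvalb itself at +0.17 ± 0.13. The lists called as higher with the preset correlation and not with an estimated one were proteasome subunits (28 of 35 higher; Psmb7 +0.27 ± 0.07), oxidative phosphorylation subunits (65 of 82 higher; Ndufb10 +0.62 ± 0.13) and the 3 Y-linked genes of the sex-linked list. Adjusted over the list alone, 0 proteasome, 0 oxidative phosphorylation and 3 Y-linked genes passed.

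By camera with its preset correlation the adjusted p was 4.04e-14 for immediate early genes, 5.60e-09 for the unfolded protein response, 1.93e-07 for heat shock proteins, 4.81e-05 for the proteasome, 7.83e-05 for sex-linked genes, 3.09e-04 for oxidative phosphorylation, 4.45e-04 for stress hormones and neuropeptides, 0.00127 for other interneurons and 0.0151 for parvalbumin markers. None of the 9 calls held with an estimated correlation, where the adjusted p was 0.0996 for immediate early genes and for stress hormones and neuropeptides, 0.102 for heat shock proteins and parvalbumin markers, 0.127 for the unfolded protein response and the proteasome, 0.143 for sex-linked genes, 0.162 for other interneurons and 0.814 for oxidative phosphorylation. By fry, 8 of the 9 lists moved on balance in their direction, with oxidative phosphorylation at an adjusted p of 0.485. The other 25 lists had an adjusted p of 0.153 to 0.975 by camera, and in 7 of them 1 member each passed over its list alone: Dlg4, which encodes PSD-95, was higher (+0.90 ± 0.22), and Hcn3, Fgf12, C1qc, Ugt8a, Drd1 and Calb1 were lower. They were the pentraxin and AMPA receptor complex, other glutamate receptors, GABA receptors and handling, ion channels, perineuronal net, synaptic vesicle release, glucocorticoid-responsive genes, neurotrophin and neuregulin signalling, synaptic adhesion, exome-implicated schizophrenia genes, cytosolic and mitochondrial ribosomal proteins, cholesterol synthesis, interferon response, complement, and markers of excitatory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelium, striatum, thalamus, cerebellum and blood.

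The calls of Fos and Egr1 were close to the threshold: leaving out any of the 6 compared libraries other than the group-housed wild-type library AGTTCC raised the adjusted p above 0.05, up to 0.0891 for Fos and 0.0883 for Egr1, with log2 changes of −1.57 to −1.94 for Egr1. With a term for Y-linked signal, chosen after seeing the data, none of the 5 genes was among the 24 called. In wild type this term coincides with housing, so it is estimated from the single-housed KO libraries alone, where only CAGATC lacks the signal. The lost calls therefore do not tell sex from housing. In a fit on the compared groups alone 4 of the 5 lost their call, among them Fhdc1 (adjusted p = 0.0691) and Egr1 (0.0724), and Fos kept it (0.0457).

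**Figure D2:**
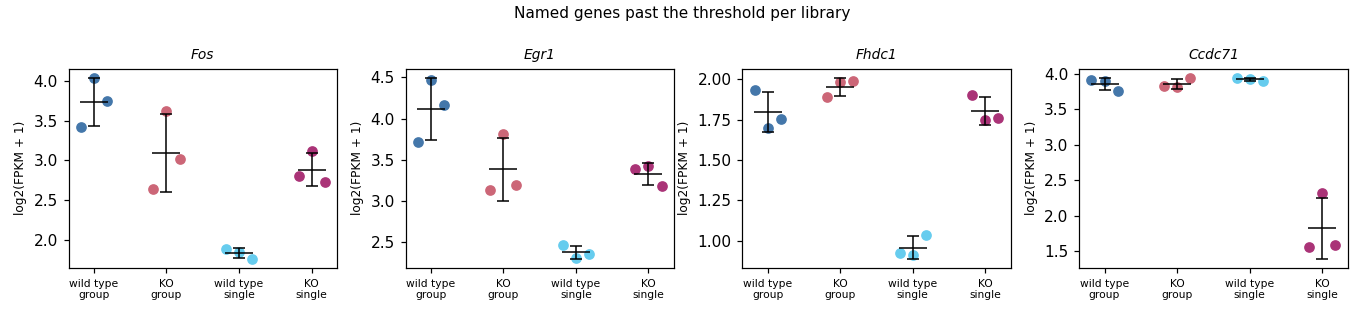
Levels of Fos, Egr1, Fhdc1 and Ccdc71 in each library, on the log2(FPKM + 1) scale, by genotype and housing. Points are libraries, horizontal bars are group means and whiskers are SD (n = 3). Fos is at 1.76 to 1.89 in single-housed wild type and at 2.64 or above in every other library, and Ccdc71 is at 1.56 to 2.32 in single-housed KO and at 3.76 or above in the other 9 libraries.

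The same housing contrast was taken within the libraries labelled KO. Ccdc71, a gene for a coiled-coil domain protein on chromosome 9 (108460527 to 108465938), fell by 2.04 ± 0.17, from 3.86 ± 0.07 to 1.82 ± 0.43 (n = 3), and was lower in 3 of 3 single-housed libraries. It was the 1 gene that passed (limma, adjusted p = 0.00250), against 554 with an unadjusted p under 0.05 and 635.8 expected. Immediate early genes did not move as a list (median −0.03, adjusted p = 0.477 by camera), with Fos at −0.21 and Egr1 at −0.05. Among named genes that did not pass, Pik3cb, the catalytic beta subunit of a class I PI3-kinase, was at −1.02 ± 0.18 and Atg7, needed for autophagosome formation, at −0.49 ± 0.09.

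By camera with its preset correlation 3 lists were called, none of which held with an estimated correlation, and fry called 0. Of 83 cytosolic ribosomal proteins 75 were higher, with a median of +0.09 and an adjusted p of 0.998 with an estimated correlation. The member with the smallest p was Rpl29 (+0.91 ± 0.19), and no member passed over all genes or when adjusted over the list alone. Microglia markers had 13 of 15 higher, with Cd68 at +0.42 ± 0.13, and the 3 Y-linked genes were higher, with 0 and 3 past the threshold over the list alone. The adjusted p was 2.02e-07, 0.0409 and 2.76e-04 by camera, and 0.998, 0.998 and 0.943 with an estimated correlation. The single-housed library CAGATC, which had no Y-linked signal, and the group-housed library GTGAAA lay at the ends of the ribosomal score, 0.122 and −0.205 (mean log2 deviation). Without GTGAAA 1 list was called, and without CTTGTA 7 were.

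KO was compared with wild type in group housing to ask what loss of Nptx2 altered at baseline. No gene passed (limma, lowest adjusted p = 0.0976), 465 genes had an unadjusted p under 0.05 where 635.8 are expected, and the authors' deposited table gave 0 genes and 510. By camera with its preset correlation 3 lists were called, all lost with an estimated correlation, and fry called 0. Immediate early genes were lower in the libraries labelled KO in 27 of 33, with a median of −0.22 and an adjusted p of 0.506 with an estimated correlation. Egr1 was at −0.73 ± 0.21 and Nr4a1, an orphan nuclear receptor induced by activity, at −0.93 ± 0.30. All 6 tested complement genes were lower, C1qc by −0.35 ± 0.10 and C1qa by −0.29 ± 0.09, and these 2 passed when adjusted over the list alone. They are made by microglia, whose own marker list did not pass by camera (adjusted p = 0.0993). C1qa, C1qb and C1qc are members of both lists, so the lists are not separate readings. Oxidative phosphorylation subunits were higher in 62 of 82, with Ndufb10 at +0.56 ± 0.13.

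The adjusted p by camera was 1.77e-06 for immediate early genes, 9.71e-04 for complement and 0.00142 for oxidative phosphorylation, and 0.506, 0.393 and 0.896 with an estimated correlation. The 3 genes with the smallest p, D130017N08Rik and the pseudogenes Hmgb1-ps1 and Gm12751, did not pass here and are described with the average effect. Without the group-housed wild-type library AGTTCC 11 genes passed, and a fit on these 6 libraries alone called 8 genes and 7 lists.

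In single housing, KO was compared with wild type to ask whether the genotype altered the state after isolation. Fhdc1, which was low in single-housed wild type, was higher in KO by 0.85 ± 0.08 (0.96 ± 0.07 in wild type, 1.80 ± 0.09 in KO). Fos at +1.05 ± 0.23 and Egr1 at +0.95 ± 0.21 did not pass over all genes (adjusted p = 0.482 each). Ccdc71 was lower in KO by −2.10 ± 0.17. In all, 5 genes passed by limma, 1 higher and 4 lower, against 1008 with an unadjusted p under 0.05, and the authors' deposited table also gave 5. The adjusted p was 0.00185 for Ccdc71 and 0.00287 for Fhdc1. The remaining 3 were named after their values were seen: the pseudogenes Gm12751 (−0.81 ± 0.07), Hmgb1-ps1 (−0.87 ± 0.09) and 2700099C18Rik (−1.01 ± 0.12).

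By camera with its preset correlation 10 lists were called, none of which held with an estimated correlation, and fry called 1, stress hormones and neuropeptides. Of 25 unfolded protein response genes 23 were higher in single-housed KO, among them Manf (+0.36 ± 0.11) and Dnajb11 (+0.26 ± 0.08). This score was 0.307 in CTTGTA and 0.109 in AGTCAA, which had high amino acid response genes, but −0.165 in CAGATC, nearer the −0.323 to −0.225 of wild type. Immediate early genes were higher in 25 of 33, with 4 past the threshold when adjusted over the list alone, Egr1, Fos, Dusp6 and Rgs2. The stress hormone and neuropeptide list had 16 of 22 higher and 2 past it, Sst (+0.64 ± 0.12) and Tac1 (+0.51 ± 0.10); Npy was at +1.07 ± 0.36. On the neuropeptide list CTTGTA and AGTCAA scored 0.0758 and 0.0757 and CAGATC 0.0254, against −0.159 to −0.0892 in wild type. Markers of other interneurons were higher in 11 of 13, heat shock proteins in 12 of 15 (Hspa1a +0.40 ± 0.11), cytosolic ribosomal proteins in 64 of 83, parvalbumin interneuron markers in 21 of 27 and microglia markers in 13 of 15 (Cd68 +0.52 ± 0.13). Proteasome subunits were lower in 27 of 35 and oxidative phosphorylation subunits in 60 of 82. Adjusted over the list alone, 1 marker each of parvalbumin interneurons, other interneurons and microglia passed, and 0 genes of the unfolded protein response, heat shock, ribosomal, proteasome and oxidative phosphorylation lists.

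By camera the adjusted p was 6.50e-08 for the unfolded protein response, 1.50e-05 for immediate early genes, 2.48e-04 for ribosomal proteins, 0.00106 for stress hormones, for heat shock proteins and for other interneurons, 0.0116 for the proteasome and for oxidative phosphorylation, 0.0184 for parvalbumin markers and 0.0217 for microglia. With an estimated correlation all 10 were lost: the adjusted p was 0.150 for stress hormones, 0.227 for parvalbumin markers, 0.263 for the unfolded protein response and for other interneurons, 0.320 for immediate early genes and heat shock proteins, 0.449 for the proteasome and 0.968 for the other 3 lists. Limited to genes off chromosome 5 with no parent gene near Nptx2, a choice made after seeing the data, 3 genes passed. In a fit on the compared groups alone Ccdc71 had an adjusted p of 0.0606. Egr1 and Cic, which had not passed, did so in that fit (limma, adjusted p = 0.0442 and 0.0130), which rests on fewer libraries.

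**Figure D3:**
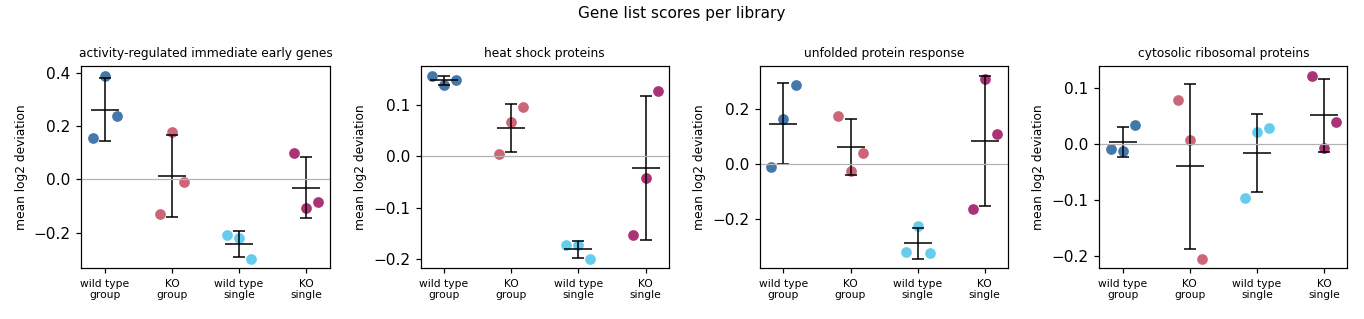
Mean log2 deviation from each gene's average over the 12 libraries, for immediate early genes, heat shock proteins, the unfolded protein response and cytosolic ribosomal proteins, in each library by genotype and housing. Points are libraries, horizontal bars are group means and whiskers are SD (n = 3). The single-housed wild-type scores for immediate early genes are −0.298 to −0.210, below all group-housed wild-type scores of 0.156 to 0.389.

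The interaction tested whether single housing acted differently in the 2 genotypes. Ccdc71 passed: its single-housing effect was +0.06 in wild type and −2.04 in KO, a difference of −2.10 ± 0.23 (limma, adjusted p = 0.0485). It was the 1 gene called, with 981 genes at an unadjusted p under 0.05. The single-housing effects of Fos and Egr1 differed by +1.70 ± 0.32 and +1.69 ± 0.29 but did not pass (adjusted p = 0.471 and 0.295), nor did that of Fhdc1 (+0.69 ± 0.11, 0.295). Of 10 lists called by camera with its preset correlation none held with an estimated correlation, and fry called 1. Immediate early genes differed in the positive direction in 28 of 33, the unfolded protein response in 23 of 25, heat shock proteins in 12 of 15, stress hormones and neuropeptides in 17 of 22, other interneurons in 11 of 13, ribosomal proteins in 65 of 83, microglia in 12 of 15 and striatal neuron markers in 9 of 11. Oxidative phosphorylation subunits differed in the negative direction in 66 of 82 and proteasome subunits in 24 of 35. Adjusted over the list alone, 3 immediate early genes (Fos, Egr1 and Dusp6), 4 neuropeptide and stress hormone genes (Tac1, Sst, Fkbp4 and Crhr1), 2 microglia markers (C1qc and Cd68) and 1 oxidative phosphorylation gene (Ndufb10) passed, and 0 in the other 6 called lists. The scores of the unfolded protein response, other interneurons and stress hormones and neuropeptides were highest in the 5 libraries with high amino acid response genes. These were GTCCGC and CCGTCC of group-housed wild type, CGATGT of group-housed KO, and CTTGTA and AGTCAA of single-housed KO. No single-housed wild-type library was among them, and how much of these differences goes with that was not tested.

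The adjusted p by camera ran from 3.25e-09 for immediate early genes to 0.0280 for the proteasome and for striatal markers. With an estimated correlation it ran from 0.0928 for stress hormones and neuropeptides, through 0.287 for immediate early genes and 0.331 for the unfolded protein response, to 0.822 for ribosomal proteins, so that none of the 10 calls held. The call of Ccdc71 ended in 10 of the 12 fits that left out a library, with an adjusted p of up to 0.238 and a difference of −1.97 to −2.35; those that kept it left out AGTTCC or CTTGTA. It ended also with a pseudocount of 0.1 (adjusted p = 0.120) and without a variance trend (0.0541).

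Averaged over genotypes, Fhdc1 was lower in single housing (−0.49 ± 0.06, limma, adjusted p = 0.0253), as was Ccdc71 (−0.99 ± 0.12, 0.0283). A530032D15Rik, named after its values were seen, was listed at 0 in 5 of 6 single-housed libraries and at 0.70 or above in all group-housed ones. These 3 were the genes called, with 1134 at an unadjusted p under 0.05. Y-linked signal was present in 5 of 6 single-housed libraries and in no group-housed one, so this average does not separate housing from sex. Within the genotypes Fhdc1 was at −0.84 in wild type and −0.15 in KO, a difference that did not pass (adjusted p = 0.295), and Ccdc71 at +0.06 and −2.04. By camera with its preset correlation 8 lists were called, none of which held with an estimated correlation, and fry called 5. Immediate early genes were lower in 28 of 33, with 15 past the threshold when adjusted over the list alone, heat shock proteins in 13 of 15 with 3, and the unfolded protein response in 24 of 25 with 0. Parvalbumin markers were lower in 19 of 27 and other interneurons in 11 of 13, whereas proteasome subunits were higher in 28 of 35, ribosomal proteins in 62 of 83 and the Y-linked genes in 3 of 3. In these 5 lists 0, 1, 0, 0 and 3 genes passed over the list alone. Several of the 8 called lists moved little within KO: the median there was −0.04 for the unfolded protein response, −0.04 for heat shock proteins, −0.03 for immediate early genes, 0.00 for parvalbumin markers and +0.01 for other interneurons, and none of these lists was called there. A difference between the genotypes is not established for them. Parvalbumin markers were not called for the interaction, and the interaction calls of the other lists named were lost with an estimated correlation. Within wild type the ribosomal list was not called (median −0.02).

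For these 8 lists the adjusted p by camera was 1.76e-11 for immediate early genes, 5.46e-07 for heat shock proteins and for the unfolded protein response, 1.14e-06 for sex-linked genes, 1.94e-05 for the proteasome, 0.0384 for parvalbumin markers and for other interneurons and 0.0454 for ribosomal proteins. With an estimated correlation the lowest adjusted p was 0.125, for immediate early genes, heat shock proteins, the proteasome, parvalbumin markers and sex-linked genes, and the others had 0.225 to 0.851. With a term for Y-linked signal none of the 3 genes was among the 17 called. That term rests on the single-housed KO libraries alone, where only CAGATC lacks the signal, so the lost calls do not tell sex from housing. Leaving out a library gave 1 gene (without the group-housed KO library ATGTCA) to 15 genes (without AGTTCC), and Ccdc71 lost its call in 7 of the 12 fits and Fhdc1 in 6. With a pseudocount of 0.1 Ccdc71 lost it as well (adjusted p = 0.0658).

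Averaged over housing, 5 genes differed between the libraries labelled KO and wild type (limma, 483 at an unadjusted p under 0.05). Fhdc1 was higher by 0.50 ± 0.06 (adjusted p = 0.00951) and Ccdc71 lower by −1.05 ± 0.12 (0.00951), both mostly from the single-housed libraries, since in group housing they differed by +0.16 and 0.00. The other 3, named after their values were seen, were lower in 6 of 6 KO libraries than in every wild-type library. D130017N08Rik is a long noncoding RNA on chromosome 5 (143758354 to 143768575), 0.78 Mb from Nptx2, and was lower by −0.90 ± 0.09. Gm12751 (−0.67 ± 0.05) and Hmgb1-ps1 (−0.78 ± 0.06) are processed pseudogenes on chromosomes 4 and 11. Their closest protein-coding matches were Polr1d, identical over the aligned part, and Hmgb1, at 96.8% identity, both on chromosome 5 within 10 Mb of Nptx2.

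Genes around Nptx2 differed between genotypes more often than genes elsewhere. Of 192 tested genes within 10 Mb of Nptx2, 12 had an unadjusted p under 0.01 (6.25%), against 79 of 12475 elsewhere (0.633%), an odds ratio of 10.5 (95% interval 5.09 to 19.7, Fisher's exact test, two-sided, p = 1.16e-08). Genes share libraries and are not independent, so this p is approximate. Among the 12, Actb, the gene of the cytoskeletal protein often used as a reference, was at −0.49 ± 0.08 (adjusted p = 0.175), Cpsf4, a subunit of the mRNA cleavage and polyadenylation machinery, at +0.68 ± 0.12 (0.201) and Eif2ak1, a kinase of the translation factor eIF2, at −0.26 ± 0.05 (0.199). Within chromosome 5 outside this window the share was 0.902% of 665 genes.

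**Figure D4:**
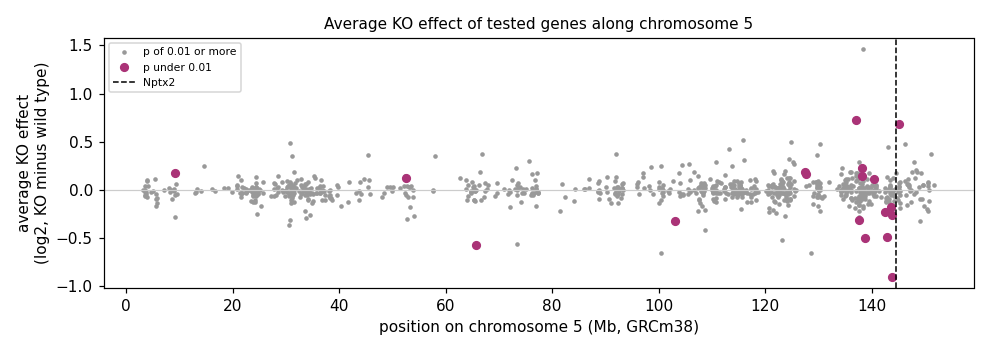
Average difference between the libraries labelled KO and wild type (log2, 6 libraries each) for every tested gene of chromosome 5, by position in Mb on GRCm38. Large purple points have an unadjusted p under 0.01, small grey points do not, and the dashed line marks Nptx2. The 12 purple points within 10 Mb of Nptx2 run from −0.90 for D130017N08Rik to +0.73 for 4933404O12Rik.

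Of the 34 gene lists, 2 were called for the average genotype effect by camera with its preset correlation, neither of which held with an estimated correlation, and fry called 0. Unfolded protein response genes were higher in 23 of 25 (median +0.14; Dnajb11 +0.16 ± 0.05) and complement genes lower in 5 of 6 (median −0.11; C1qb −0.18 ± 0.08). By the group means, KO was higher on the first list in single housing only: the score was 0.146 ± 0.149 in wild type and 0.0608 ± 0.102 in KO under group housing, and −0.290 ± 0.0560 and 0.0833 ± 0.237 under single housing (mean ± SD, n = 3). The interaction call of this list was lost with an estimated correlation, so a difference between the housing conditions is not established. Of the libraries with high amino acid response genes, single-housed wild type held 0 and single-housed KO 2. The complement median was −0.23 in group housing and +0.02 in single housing. The 2 lists had an adjusted p of 1.15e-04 and 0.0460 by camera and of 0.529 for both with an estimated correlation. No member passed when adjusted over the list alone. Off chromosome 5 and with no parent gene near Nptx2, 2 genes passed, and without CTTGTA 9 genes and 7 lists did; Actb then had −0.56 and an adjusted p of 0.0193.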

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

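All the tests of explanations in this part were chosen after the pattern was seen, while the regroupings of libraries were written before. The interaction test called 1 gene and 10 lists for a single-housing effect that differed between the genotypes. None of the 10 list calls held with an estimated correlation (lowest adjusted p = 0.0928), and fry called 1 list. Among the 10 lists, the unfolded protein response, other interneuron and neuropeptide scores also parted the libraries with high amino acid response genes from the rest. The groups hold unequal numbers of those libraries. Ccdc71 differed by −2.10 on the log2 scale. The median differences were +0.380 for immediate early genes, +0.186 for stress hormones and neuropeptides, −0.0807 for oxidative phosphorylation subunits, +0.108 for cytosolic ribosomal proteins, +0.373 for the unfolded protein response, +0.212 for heat shock proteins, −0.0587 for proteasome subunits, +0.205 for other interneuron markers, +0.187 for microglia markers and +0.258 for striatal neuron markers. Of 100 regroupings of the 12 libraries, 67 called as many genes (1 real, highest other 31) and 11 as many lists (10 real, highest other 15), so chance could not be excluded for either count. What the regrouping with 31 genes separates was not examined.

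The fall of immediate early genes in single-housed wild type (score change −0.503 ± 0.094, SE) coincided fully with Y-linked signal. A sex difference alike in both genotypes would lower the list also in KO libraries with that signal, but their change from group housing was −0.110 ± 0.105, which lies 2.79 SE above the wild-type change and argues against it as the whole source. It leaves a part open: among single-housed KO libraries the list score was −0.109 and −0.0857 in the 2 with Y-linked signal and 0.10 in CAGATC without it. The genotype difference of this list, on which the argument rests, was itself lost with an estimated correlation (adjusted p = 0.287). Less RNA from excitatory neurons would lower their markers as well. That list changed by −0.044 ± 0.059, and lay above 0.5 of the immediate early change by 2.26 SE. This bears on the amount of such RNA, not on immediate early levels within it, and no RNA before pulldown was analysed. A sex difference present only in wild type, one that accounts for part of the change, an effect of housing, and differences in handling before dissection stay open, and the design cannot separate them. Of the 10 splits of the 6 wild-type libraries, 2 called as many genes (5 real, highest other 5) and 3 as many lists (9 real, highest other 11), too few splits for a share under 0.05.

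The excess of genotype differences near Nptx2 is what a segment of another strain carried along with the targeted allele may give, with an odds ratio of 10.5 for the window. Normalization or library composition would spread differences over the genome, and the lower 95% limit of 5.09 argues against it. Of window genes with p under 0.05 in group housing, 72% (18 of 25, 95% interval 50.6 to 87.9) kept their sign in single housing against 40.4% elsewhere, which leaves the size of a constant effect open. Reads shared with copies of segment genes stay open for the pseudogene calls. Of 37 pseudogenes with a parent in the window 7 had p under 0.01, against 7 of 890 others (odds ratio 29.0, the first test chosen), but these 7 have the parents Hmgb1 (6 of them) and Polr1d, whose places prompted the idea. Without the pseudogenes of these parents it was 0 of 24 against 7 of 890 (Fisher's exact test, upper 95% limit of the odds ratio 27.0), too few to decide. Wrong genotype labels of single libraries are argued against for 11 libraries. The 5 KO libraries other than CTTGTA had positions of at least 0.868 between the wild-type mean (0) and the KO mean (1), and no wild-type library exceeded 0.291. This scale is set by the labels, so an exchange of all labels would part the libraries equally well and was not tested. The 12th library, CTTGTA, at 0.436, is undecided.

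For the counts of genes called, the other regroupings gave these values. For the average effect of KO, 2 of 100 regroupings of the 12 libraries, the real one among them, called as many genes (5 real, highest other 6), a share under 0.05. It was the lowest of the shares taken over the 12 libraries and was not adjusted for their number, so it argues against chance only weakly. As many lists were called by 84 (2 real, highest other 16). For the average effect of single housing, 22 of 100 called as many genes (3 real, highest other 4) and 32 as many lists (8 real, highest other 20), so chance could not be excluded. The 3 remaining comparisons have 10 splits each, too few for a share under 0.05. For KO in single housing 3 splits called as many genes (5 real, highest other 6) and 2 as many lists (10 real, highest other 14). For single housing in KO 7 splits called as many genes (1 real, highest other 7) and 10 as many lists (3 real, highest other 15). For KO in group housing 10 splits called as many genes (0 real, highest other 7) and 9 as many lists (3 real, highest other 7).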

How the results depend on the processing

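Depth is unknown, so no limit from it can be given. No paired analysis was possible because the columns carry no replicate number, and the planned replicate block was not run. Repeating quantile normalization moved almost nothing and tests nothing. Median-ratio scaling kept all 14 counts of genes and lists. Nptx2 in KO kept its positive sign and stayed above the threshold in all alternatives of both housing conditions.

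Without a filter 1 list was called for the average effect of KO. With a pseudocount of 0.1, 2 genes were called for single housing in KO and 0 for the interaction, and without a variance trend or under the authors' settings 0 for the interaction. In fits on the compared groups alone, 8 genes were called for single housing in wild type (1 shared with the 12-library fit), 16 for single housing in KO (1 shared), 8 genes and 7 lists for KO in group housing, and 9 genes for KO in single housing (2 shared). These fits rest on fewer libraries. With a term for Y-linked signal, added after seeing the data, 24 genes were called for single housing in wild type, 17 for single housing in KO, 1 for KO in group housing, 9 for KO in single housing and 17 for the average effect of single housing. That term is estimated from the single-housed KO libraries alone, where only CAGATC lacks the signal. Off chromosome 5 and with no parent near Nptx2, 3 genes were called for KO in single housing and 2 for the average effect of KO, by construction of the gene set. The cause of the other changes was not tested.

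Leaving out 1 library gave 2 to 9 genes (without ACAGTG and AGTTCC) and 9 to 12 lists for single housing in wild type. For single housing in KO it gave 2 to 6 genes (most without CAGATC) and 1 to 7 lists. CAGATC is the single-housed KO library without Y-linked signal. Without it Ddx3y and Eif2s3y passed in that comparison (limma, adjusted p = 1.95e-07 and 2.66e-08), so the added calls include Y-linked genes. For KO in group housing it was 0 to 11 genes (most without AGTTCC) and 3 to 7 lists (most without CGATGT). For KO in single housing it was 5 to 9 genes (most without GCCAAT or CAGATC) and 7 to 11 lists. The interaction had 0 to 8 genes (most without AGTTCC) and 7 to 11 lists. The average effect of single housing had 1 to 15 genes (without ATGTCA and AGTTCC) and 5 to 12 lists (fewest without AGTCAA). The average effect of KO had 4 to 12 genes (most without AGTTCC) and 1 to 7 lists (most without CTTGTA).

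Log2 changes near 0 that turned sign when a library was left out, none past the threshold, ran as follows. For single housing in wild type, Nptx2 was at −0.131 to 0.0266 and Nptxr at −0.0711 to 0.0420. For single housing in KO, Nptx2 was at −0.135 to 0.0492, Nptx1 at −0.137 to 0.00754, Nptxr at −0.00848 to 0.0615 and Pvalb at −0.267 to 0.0484. For KO in single housing, Nptxr was at −0.0730 to 0.0389. For the interaction, Nptx2 was at −0.0625 to 0.122, Nptxr at −0.00622 to 0.107 and Gria4 at −0.0319 to 0.0526. For the average effects, Nptxr with housing was at −0.0177 to 0.0389, Pvalb with housing at −0.0493 to 0.108 and Pvalb with genotype at −0.128 to 0.0298. No other gene chosen by the naming rule turned sign under the alternatives written before the data were examined, which were not run for the remaining genes named in the text.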

Other observations

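Genes of the amino acid response, which ATF4 switches on when amino acids run short, had separated levels across the libraries. All tests in this part were chosen after the pattern was seen, and the list of 34 genes was written then. The list score was 0.573 in the group-housed KO library CGATGT, 0.483 in single-housed KO AGTCAA, 0.423 and 0.389 in group-housed wild type GTCCGC and CCGTCC, and 0.358 in single-housed KO CTTGTA. The other 7 libraries lay between −0.344 and −0.283. Chac1, which degrades glutathione, was at 4.82 to 5.16 in the first 5 libraries and at 3.28 to 3.63 in the other 7; Phgdh, the first enzyme of serine synthesis, was at 4.13 to 4.51 and 2.08 to 2.54, Mthfd2, of mitochondrial folate metabolism, at 3.82 to 4.07 and 2.68 to 2.84, and Asns, asparagine synthetase, at 7.31 to 7.46 and 6.32 to 6.58. Hspa5, the chaperone of the endoplasmic reticulum, did not follow this order, with 5.50 in GTCCGC of the first 5 and 6.43 in AGTTCC of the other 7. The scores of 3 of the fixed lists parted the same 5 libraries from the other 7: the unfolded protein response (0.109 to 0.307 against at most 0.0372), other interneuron markers (0.0637 to 0.230 against at most 0.0283) and stress hormones and neuropeptides (0.0437 to 0.138 against at most 0.0254). The first shares Chac1, Asns, Atf5, Atf4 and Ddit3 with this response. The groups hold unequal numbers of such libraries. Group-housed wild type held 2 of 3, single-housed wild type 0, group-housed KO 1 and single-housed KO 2. How much of the movement of these 3 lists goes with that was not tested. The first principal component of all tested genes, with 14.1% of the variance, parted the same libraries. It was at 6.36 to 12.5 in these 5 libraries and at −14.8 to 4.16 in the other 7. The split is therefore not limited to these lists, and gene counts of the comparisons may carry it, which was not tested. AGTTCC, without which several comparisons called the most genes, is the group-housed wild-type library among the other 7.

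Housing or genotype as the whole source would keep the libraries of a group together, but the widest range within a group was 99.1% of the range over the 12 libraries, and the groups held 25.4% of the variance (permutation p = 0.586). The list was written after the split across groups was seen, so a wide range was fixed in advance and describes the split without testing it. The permutation p was the first test chosen; the range replaced it after both values were seen, because a p that misses a threshold excludes nothing. The sex of the animals would place the 5 libraries with Y-linked signal at an end of the order, and 3 of them were out of place. A batch of dissection, diet or library preparation stays open as a candidate source, since the labels name none.

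The tests of this library were chosen after its values were seen. The single-housed KO library CTTGTA stood between genotypes near Nptx2, with a position of 0.436. Under the limit first written, 0.5, it counts as nearer wild type and so as a possible wrong label. After that was seen the limit was replaced by the mean plus 2 SD of the wild-type positions, 0.378, which it exceeds narrowly. The 2 limits give opposite readings, so whether its label is wrong stays undecided. Gene by gene its values went both ways. These genes were chosen by the average KO effect with this library counted as KO, which favours genes where it is like KO. Those behind its position were chosen without it. It lay within the wild-type range and outside that of the other KO libraries at Actb (8.49; wild type 8.31 to 8.66, other KO 7.88 to 8.24) and Hmgb1-ps2 (3.61; 3.54 to 3.70 and 3.40 to 3.58), and likewise at 4933404O12Rik, Actl6b, Cnpy4, A430033K04Rik, Radil and Fam220a. It lay within the range of the other KO libraries and outside that of wild type at Eif3b (5.34; wild type 5.17 to 5.30, other KO 5.27 to 5.37), Ap4m1 (2.89; 2.65 to 2.88 and 2.83 to 3.08), Cpsf4 (2.39; 1.75 to 2.02 and 2.36 to 3.07) and Gm12751 (2.41; 2.94 to 3.33 and 2.36 to 2.60), and likewise at Gm13577, Hmgb1-ps1 and Gm5527. At Hmgb1-ps7 and Gm37164 it lay beyond the other KO libraries on the side away from wild type. At D130017N08Rik it had 3.08, between the other KO values of 2.44 to 2.70 and the wild-type values of 3.53 to 3.60, and it lay between them at Eif2ak1 too. Most genes on the Actb side of Nptx2 were thus like wild type, except Ap4m1, Eif3b and, nearest Nptx2, D130017N08Rik and Eif2ak1, and most beyond it like the other KO libraries or further out, with Hmgb1-ps2 as the exception. The pseudogenes of Hmgb1 share 1 parent, and all these values come from 1 library.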
